A study of Solanum lycopersicum and Oryza sativa Japonica Group with 145 samples.

How the data were processed

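TRAP libraries of tomato and rice roots and ATAC libraries of tomato root tips were analysed from the tables and peak lists the submitters made. The deposited count tables hold estimated counts per gene, 1 column a library, with 35768 tomato and 37849 rice genes. Trim Galore 0.4.5, kallisto 0.43.1, FastQC, Bowtie2 and HOMER are named in the submitters' processing notes without roles, as is the rice build IRGSP-1.0. The tomato annotation is not given in the sources used here. Estimated counts split reads between similar sequences by a model, so genes with near-identical copies are uncertain, and the strand used in counting is not given. The labels' protocols describe poly(A) selection and random-primed libraries. The authors' ATAC files list peak positions, called per library on build SL3.0 (from the chromosome names), with no score, height or p per peak in the columns used here.

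Samples were grouped by the line named in their labels and by experiment. 1 pot library had conflicting labels and entered no comparison. The adventitious meristematic cortex group had 1 library and entered the pot fit without a contrast. Comparing replicate pairs within groups by a chi-square over genes with at least 20 counts, none of 186 pairs was identical and the lowest chi-square per degree of freedom was 2.96, so no library was counted as a repeat deposit. This does not test whether libraries that share a letter came from separate material.

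Estimated counts were rounded to whole numbers. Each experiment was fitted once with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM factors and robust quasi-likelihood dispersions over group means, and without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and a log2 fold change of at least 1. CPM values are scaled by TMM factors, so a dominant gene can exceed its plain share of counts. Standard errors were computed as the log2 fold change over the square root of its F statistic. Samples, contrasts, alternatives and the rule for named genes were fixed before the data were examined. That rule took called genes with a mean of at least 5 CPM in the higher group, or over the compared groups for lower genes, and the log2 CPM of every library of the tested group (with a prior count of 2) on the called side of the mean of log2 CPM over the compared groups, ranked by log2 fold change. A mean on the log scale lies below that of CPM, so a library can pass this rule and lie under the compared mean CPM, as given with those genes. The reference table of gene names matched 0 tomato gene identifiers, so identifiers are given as in the files, at most 2 higher and 2 lower a contrast, without names or functions. For the same reason the marker gene lists planned for cell division, suberin, Casparian strip and other themes were not tested, nor were promoter peaks of enriched genes.

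The fits were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed 4-fold or 16-fold. The plate contrast for the epidermis found 52% of 4-fold and 85% of 16-fold changes over 20152 genes, with 49 of 186 calls false, and with other seeds 55 of 197 and 45 of 189. Of unchanged genes without a count in at least 1 group of the contrast, 26% had p under 0.05, against 7.79% of all unchanged genes. The design was kept as written and an alternative was added in which the other marked populations form 1 group. It was picked among several candidate fits by their behaviour on simulated counts, before its call counts on the real plate table were seen. It found 45% and 82% of the changes, with 8 of 135 calls false. Apart from the changed genes, all simulated groups shared 1 mean per gene, whereas the real populations differ from one another. These rates therefore need not hold for the real counts, least of all where differing populations are joined. The field endodermis contrast made 5 false calls of 178, the rice endodermis contrast 4 of 198, the interaction contrast for the endodermis 4 of 62 (3% and 55% found) and the pot contrast 2 of 41. The share of unchanged genes with an empty group that had p under 0.05 was higher there than on plates, at 63.8% for the interaction (47 genes with an empty group) and 41.9% for the pot contrast (1020 genes).

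Other settings chosen beforehand were DESeq2 1.42.0, DESeq2-style size factors in edgeR, no low-count filter, no fold minimum, comparison with the constitutive lines, the library letter or number as a block, and leaving out each library. Added after seeing the data were a local dispersion trend for DESeq2 in rice, where the default parametric trend did not converge reliably, the joined populations, plate libraries Ta and Tb summed within their group, the ATAC letters of the titles, a fit without the libraries under 500000 counts, and the share of counts in the 10 most abundant genes as a covariate. Group labels were also redistributed over libraries at random, and again with the population that differed most (plate exodermis, field endodermis or rice RSS1) left in place. Splits of plate libraries numbered 40 as designed and 25 to 44 when joined, where a first round of draws was extended after its counts were seen and every draw of both rounds was counted.

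Peak sets were compared with Python 3.11.15 and numpy 2.4.6 by the Jaccard index of covered bases, and population labels were permuted 100000 times. Library depth before peak calling was not used here, so peak numbers are not corrected for it. Intervals and limits from counts cover counting error only. Plots were drawn with matplotlib 3.10.9.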

Results

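The series profiled marked cell populations of tomato (cultivar M82) and rice roots with a pair of assays. In TRAP, a tagged ribosomal protein is expressed under a promoter active in part of the root, and the RNA bound to the tagged ribosomes is purified and sequenced. In INTACT-ATAC, tagged nuclei are captured from the same kinds of lines and open chromatin is marked by a transposase. Of the 145 libraries, 56 were TRAP libraries from root tips of plate-grown tomato seedlings aged 3 to 5 days, in 10 marked populations and 2 lines with constitutive promoters (35S and ACT2). A further 22 came from tomato roots in the field at 2 months (endodermis, meristematic zone, meristematic cortex and 35S), 12 from potted tomato plants at 1 month, 16 from rice seedlings aged 7 days, and 39 were ATAC libraries of tomato root tips. Groups of plate libraries held 4 to 6 libraries each, field groups 5 or 6, and rice groups 3 or 4. Replicates are described by the submitters as independent. The quiescent centre and vasculature groups each hold a pair of libraries with 1 letter (Ta and Tb), and the labels do not say whether these came from separate material. The 4 rice meristematic cortex libraries are 2 replicates of each of 2 lines, so their spread includes that between lines.

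Depth differed widely between libraries. Totals on plates ran from 14034 to 74276216 counts, with a median of 6212028, and 8 of the 56 libraries held under 500000 counts. Field totals ran from 416341 to 13984058 counts (median 7129030), pot totals from 1271128 to 11261783 (median 3475206) and rice totals from 1637460 to 12490912 (median 4261618). The shallowest plate libraries were in the phloem (lowest 14034 counts), vasculature (21196), quiescent centre (109687), cortex (131914) and xylem (210277) groups.

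A few genes took much of the RNA in most marked plate and rice populations and little of it in the constitutive lines. The 10 most abundant genes of the plate table held 3.32% ± 1.47 of counts in 35S (SD, n = 4) and 3.07% ± 0.196 in ACT2 (SD, n = 4). They held 13% ± 1.28 in the meristematic zone (SD, n = 4), 53.4% ± 5.84 in the endodermis (SD, n = 4), 55.1% ± 5.97 in the quiescent centre (SD, n = 6) and 55.5% ± 6.35 in the xylem (SD, n = 5). The gene Solyc08g081250.3.1 held 30.1% ± 4.24 of xylem counts (SD, n = 5) and 1.26% ± 0.104 of ACT2 counts (SD, n = 4). Field endodermis libraries had 42.5% ± 3.53 of their counts in the 10 most abundant genes of the field table (SD, n = 5), against 11.6% ± 5.16 in field meristematic cortex (SD, n = 5), 2.94% ± 0.394 in field meristematic zone (SD, n = 6) and 1.66% ± 0.299 in field 35S libraries (SD, n = 6). In rice the share was 82.9% ± 2.07 in the meristematic cortex (SD, n = 4), 19% ± 1.82 in RSS1 (SD, n = 3) and 5.61% ± 1.01 in 35S (SD, n = 3), and Os06t0175500 alone held 56.5% ± 3.56 of meristematic cortex counts (SD, n = 4).

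**Figure D1:**
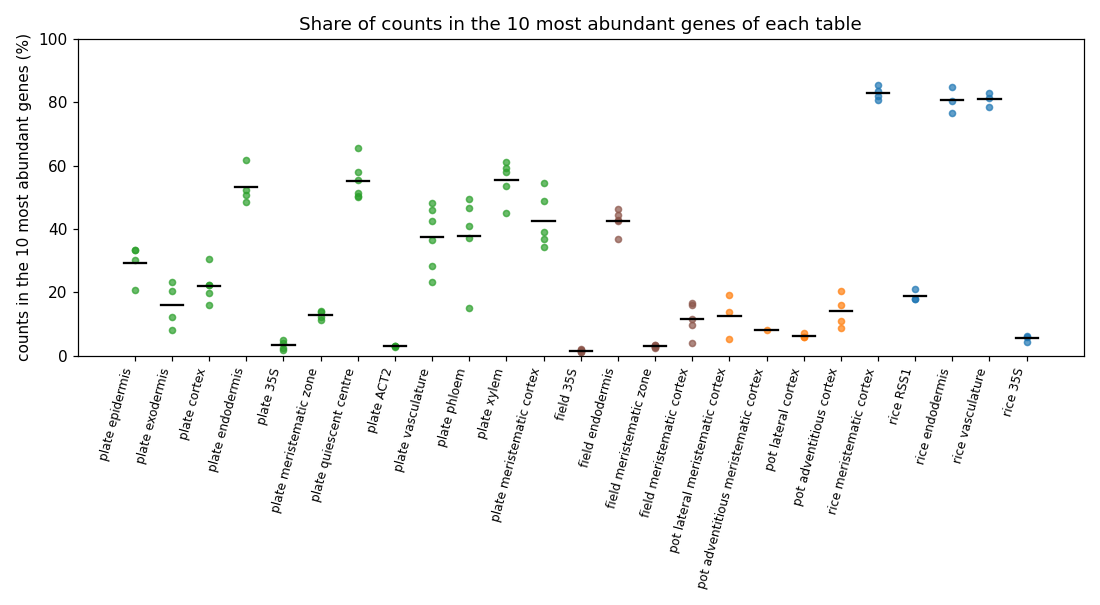
Percent of counts in the 10 most abundant genes of each count table (y axis) by group (x axis); points are libraries, black bars are group means, and colours separate plate, field, pot and rice libraries. The plate constitutive lines average 3.32% (35S) and 3.07% (ACT2), and rice meristematic cortex, endodermis and vasculature average 82.9%, 80.6% and 80.9%.

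Each plate population was compared with the mean of the other 9 to ask which RNAs were enriched in it. The populations overlap, which dilutes these contrasts. The vasculature holds phloem and xylem, and the meristematic zone holds meristematic cortex and quiescent centre. All counts of called genes come from edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1, over 20520 genes. In simulated plate counts this contrast made 186 calls for the epidermis, of which 49 were false (26.3%), 46 of them higher. In the real plate counts, 3798 genes had no count in at least 1 marked population. For each population the count is therefore given first as designed and then with the other 9 populations joined into 1 group. This alternative was chosen after that simulation, where it made 135 calls with 8 false. The other 9 populations did not differ from one another in the simulation, so these rates need not hold for the real counts. The balance of higher and lower calls depended on the tool, so the share of higher calls in DESeq2 stands beside that in edgeR. With the share of the 10 most abundant genes as a covariate, the designed count fell by more than 1.5 times in every population except the epidermis. With the library letter as a block, the designed count fell by more than 1.5 times in every population, as listed in the part on processing. Against 35S and ACT2 it was 493 for the epidermis, 876 for the exodermis, 146 for the meristematic zone, 1025 for the vasculature and 1720 for the xylem, and within 1.5 times for the others. Mean CPM is given for genes with an empty group, where a fitted fold has no bound, and a mean of 0 over a group allows a level of up to 3 counts in its summed depth, scaled by TMM factors like the means.

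The quiescent centre, the small organising group of cells in the root meristem, was rich in Solyc03g096300.3.1, which stood at 868 ± 141 CPM there (SD, n = 6) and at no more than 3.72 CPM in any other marked population, a log2 fold change of 12.14 (SE 0.54, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.69e-22), with all 6 libraries above the compared mean. Solyc04g047727.1.1 averaged 30.1 ± 41.7 CPM (SD, n = 6) beside 29.1 CPM in the endodermis, with library Tb, at 0.511 CPM, under the compared mean of 6.14 CPM. Solyc09g005470.3.1 and Solyc08g006760.3.1 had no count in any of the 6 quiescent centre libraries (up to 0.439 CPM possible) and averaged 6.6 and 10.6 CPM over the other populations. Of these 4 genes Solyc03g096300.3.1 alone passed when the other populations were joined. In all, 1603 genes were higher and 448 lower as designed (78.2% higher, 60.8% in DESeq2), and 159 higher and 132 lower with the other populations as 1 group. Higher calls as designed were 1048 or 1036 without quiescent centre library O or P.

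Phloem libraries, from the sugar-conducting tissue, held RNAs barely seen elsewhere. Solyc04g058080.3.1 averaged 67.5 ± 43.6 CPM in the phloem (SD, n = 5) and at most 2.04 CPM elsewhere, in the vasculature line, whose cells include phloem. Solyc09g011027.1.1 averaged 27.8 ± 12.1 CPM (SD, n = 5) and had no count in the other 9 populations. Solyc08g079190.1.1, at 63.5 CPM in the cortex, and Solyc09g074630.3.1, at 20.2 CPM in the quiescent centre, had no count in the phloem (up to 0.159 CPM possible). The phloem count was 1345 higher and 292 lower as designed (82.2% higher, 56.1% in DESeq2), and 396 higher and 74 lower with the other populations as 1 group, the highest joined count of the 10. Lower calls as designed were 150 or 133 without phloem library Q or T. In the vasculature, Solyc11g072580.2.1 (46 ± 32.7 CPM, SD, n = 6, log2 fold change 4.51, SE 0.63) and Solyc06g076330.3.1 (51.5 ± 24.7 CPM, SD, n = 6, log2 fold change 4.50, SE 0.57) were higher, with Benjamini-Hochberg adjusted p of 8.41e-08 and 5.18e-09 in edgeR's quasi-likelihood test. Solyc09g061440.3.1 and Solyc05g051700.3.1 had no vasculature count (up to 0.255 CPM possible) and averaged 11.2 and 8.8 CPM elsewhere. Vasculature calls numbered 1311 higher and 271 lower as designed, and 149 higher and 41 lower when joined. DESeq2 called 1029 there, with 47.2% higher against 82.9%. Higher calls as designed were 848 without vasculature library R, and lower calls 147 without library Ta.

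In xylem libraries, from the water-conducting tissue, Solyc02g080610.3.1 averaged 12.3 ± 9.31 CPM (SD, n = 5) against 9.68 CPM in the meristematic cortex, and Solyc02g011680.3.1 averaged 12.7 ± 14.3 CPM (SD, n = 5) against at most 2.97 CPM elsewhere. Each had 4 of 5 libraries above the compared mean of 1.95 and 0.611 CPM, with library N at 0.834 CPM and library K at 0.473 CPM under it. Solyc12g011130.2.1 fell by 4.76 on the log2 scale (SE 1.37) and Solyc03g121360.1.1 fell by 4.65 (SE 1.46), with Benjamini-Hochberg adjusted p of 0.023 and 0.042 in edgeR's quasi-likelihood test. None of these 4 passed with the other populations joined. The counts were 786 higher and 189 lower as designed and 19 higher and 4 lower when joined, and DESeq2-style size factors raised the designed count to 1865 and moved the share of higher calls from 80.6% to 97.5% (82.3% in DESeq2). Without the low-count filter the count was 1919. Without endodermis library N 1275 genes were higher and 114 lower, and without xylem library T 90 were lower.

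Among the outer layers, epidermis libraries were richer in Solyc03g124020.1.1 (22.5 ± 6.27 CPM, SD, n = 4, against at most 5.04 CPM elsewhere) and in Solyc01g010140.1.1 (13.1 ± 11.6 CPM, SD, n = 4, against at most 2.24 CPM). Solyc04g008385.1.1 and Solyc04g039980.3.1 had no epidermis count (up to 0.0385 CPM possible) and reached 39 and 24.8 CPM in the meristematic cortex, but neither passed when joined. The exodermis, the outermost cortical layer, held 5.44 ± 3.28 CPM of Solyc08g082210.3.1 (SD, n = 4) against at most 0.191 CPM elsewhere. Solyc08g078920.2.1 averaged 22.9 ± 24 CPM in the exodermis (SD, n = 4) and 13.2 CPM in the cortex, and did not pass when joined. Solyc09g011720.3.1 and Solyc11g039990.1.1 had no exodermis count (up to 0.0251 CPM possible), against 41.4 CPM in the phloem and 13.5 CPM in the quiescent centre at most, and neither passed when joined. Epidermis calls were 1229 higher and 125 lower as designed and 293 higher and 22 lower when joined. DESeq2 called 876 in the epidermis, with 43.8% higher against 90.8%, so most calls there were lower. As designed, 70, 64 and 63 were lower without epidermis libraries G, J and N. Without the low-count filter the epidermis count was 2419. Exodermis calls were 1786 higher and 532 lower, and 346 higher and 102 lower when joined. DESeq2-style size factors moved the exodermis share of higher calls from 77% to 66.6%, and DESeq2 itself to 33.9%. Without exodermis library G or P the designed count was 1519 or 1523, and without G, J and P the lower calls were 211, 328 and 188.

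The cortex and the meristematic cortex gave many calls as designed and few when joined. In the cortex, Solyc04g076190.1.1 averaged 39.6 ± 45.2 CPM (SD, n = 5) with 119 CPM in library R alone, and Solyc03g095810.3.1 averaged 7.79 ± 6.16 CPM (SD, n = 5). Solyc02g005115.1.1 and Solyc07g043700.2.1 had no cortex count (up to 0.0296 CPM possible) and averaged 7.02 and 9.45 CPM elsewhere. In the meristematic cortex, Solyc12g056810.2.1 averaged 20.2 ± 20.2 CPM (SD, n = 5), with library K at 2.13 CPM under the compared mean of 2.66 CPM, and the mean of Solyc08g081350.2.1, 13.3 ± 28.2 CPM (SD, n = 5), came from library S at 63.8 CPM, while libraries K, M and T, at 0.304 to 0.409 CPM, lay under the compared mean of 1.53 CPM. Solyc10g083330.1.1, without a meristematic cortex count (up to 0.193 CPM possible) and at 1.49 to 17.6 CPM in the other populations, was the only named gene of these 2 populations that also passed when joined; Solyc01g110035.1.1, at 1.82 to 15.1 CPM elsewhere, did not. Cortex calls were 1314 higher and 166 lower, falling to 35 and 2 when joined, and were 957 in all without library R (855 higher and 102 lower) and 2253 without the low-count filter. Lower cortex calls were 79 without cortex library G and 83 without T. In DESeq2 49.6% of cortex calls were higher, against 88.8%. Meristematic cortex calls were 1683 higher and 188 lower, falling to 49 and 3 when joined, and were 953 in all without library S (873 higher and 80 lower), and 114 were lower without library K. DESeq2 called 742 there, with 46.1% higher against 90%.

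The endodermis, the inner barrier layer around the vascular tissue, had 2439 genes higher and 138 lower as designed, and 293 higher and 16 lower when joined. DESeq2 called 970 there, with 52.7% higher against 94.6%, and 255 were called with the abundant gene share as a covariate. Solyc12g038350.2.1 averaged 20.7 ± 15.5 CPM (SD, n = 4) against at most 7.11 CPM elsewhere. Solyc09g072640.3.1 averaged 20.1 ± 36.3 CPM (SD, n = 4), with 74.4 CPM in library G and no more than 4.03 CPM in the other 3 endodermis libraries. Solyc07g065230.1.1 and Solyc10g044520.2.1 had no endodermis count (up to 0.117 CPM possible), and the former stood at 2.67 to 11.6 CPM in every other population. Solyc10g044520.2.1 did not pass when joined. Without endodermis library G or R the designed count was 1449 or 1676, with 1344 or 1610 higher, and without L, N and R the lower calls were 305, 80 and 66. In the meristematic zone, Solyc02g086640.3.1 averaged 9.97 ± 10.2 CPM (SD, n = 4) against at most 0.89 CPM elsewhere, and Solyc07g064310.2.1 averaged 7.56 ± 3.25 CPM (SD, n = 4) against 4.49 CPM in the vasculature. Solyc01g060020.3.1 and Solyc02g064802.1.1 had no meristematic zone count (up to 0.045 CPM possible) and averaged 9.82 and 8.43 CPM elsewhere. Solyc07g064310.2.1 and Solyc01g060020.3.1 did not pass when joined. Meristematic zone calls were 935 higher and 291 lower as designed and 66 higher and 42 lower when joined. DESeq2-style size factors moved its share of higher calls from 76.3% to 56.9%, and DESeq2 itself to 15.6%. The count was 2078 without the low-count filter, and the designed count was 799 or 730 without library O or R. Higher calls were 589 without R, and lower calls 179, 148, 127 and 141 without H, L, O and R.

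**Figure D2:**
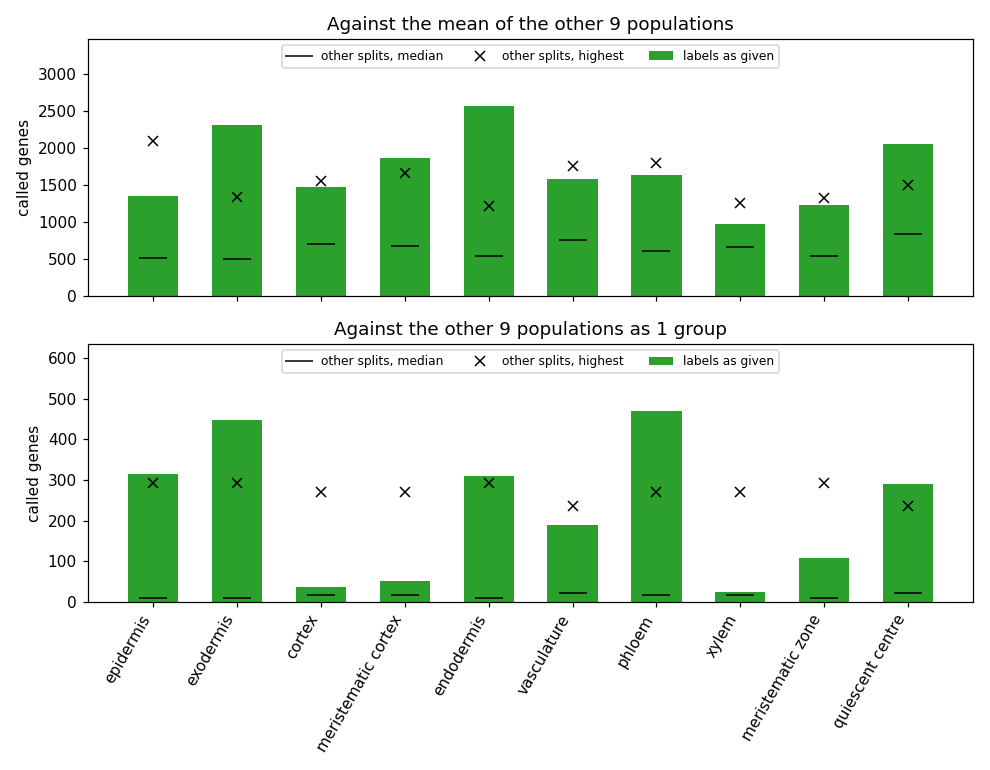
Called genes (y axis) in each plate population (x axis), as designed (upper) and with the other 9 populations joined into 1 group (lower); bars are the counts under the given labels, black dashes and crosses the median and highest counts under other splits of the libraries. Joined counts run from 23 (xylem) to 470 (phloem), and the highest joined count of another split is 292.

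The exodermis and the endodermis, the barrier layers of the tomato root, were compared directly. Solyc10g044520.2.1 averaged 61 ± 23.1 CPM in the exodermis (SD, n = 4) and Solyc03g111830.3.1 averaged 10.8 ± 9.71 CPM (SD, n = 4), and neither had a count in the endodermis. Solyc03g115710.1.1 (39.3 CPM) and Solyc04g047727.1.1 (29.1 CPM) were read in the endodermis and had no count in the exodermis. In all 453 genes were higher in the exodermis and 889 in the endodermis. Without exodermis libraries G, J, M and P these were 269 and 298, 297 and 424, 325 and 513, and 224 and 227, and without endodermis libraries N and R 282 and 815, and 302 and 531. The total was 567, 721, 838 and 451 without the same exodermis libraries and 833 without endodermis library R, 33 with the share of the 10 most abundant genes as a covariate, and 2430 in DESeq2.

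Compared pair by pair in the same fit, plate populations were called different in 1 gene to 1782 genes. The xylem and the quiescent centre differed in 1 gene, the meristematic cortex and the xylem in 2, the meristematic cortex and the endodermis in 7, the endodermis and the xylem in 9, the epidermis and the meristematic zone in 23, and the exodermis and the cortex in 25. The exodermis differed from the quiescent centre in 1782 genes, from the meristematic cortex in 1675 and from the phloem in 1645. These pairwise counts were chosen after the data were seen. The 10 most abundant genes held 55.5% of xylem, 55.1% of quiescent centre, 53.4% of endodermis and 42.7% of meristematic cortex counts, against 16% in the exodermis. The epidermis and the meristematic zone, at 29.4% and 13%, differed in few genes all the same. The xylem and the quiescent centre also hold 2 libraries each under 500000 counts. That share was not run as a covariate for the pairs named here, so few calls do not show that populations are alike.

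In the field, the endodermis stood far apart from the other marked populations, with 3146 genes higher and 2455 lower of 18532 tested. Solyc12g038350.2.1, also called in the plate endodermis, averaged 323 ± 224 CPM (SD, n = 5) against at most 0.572 CPM in the meristematic zone and meristematic cortex (log2 fold change 9.36, SE 0.39, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.7e-18). Solyc04g051427.1.1 averaged 90.3 ± 37.9 CPM (SD, n = 5) against at most 0.199 CPM. Solyc03g111400.1.1 and Solyc02g091900.3.1 had no count in the 5 endodermis libraries (up to 0.281 CPM possible) and averaged 25.5 and 12 CPM in the other marked populations. With the other populations joined, 2824 were higher and 2522 lower. With the share of abundant genes as a covariate, 182 genes were called.

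Field meristematic zone libraries differed from the other marked populations in 1407 genes higher and 1183 lower, but in 13 genes from the constitutive 35S line. Pair by pair, also chosen after the data were seen, the meristematic zone differed from the meristematic cortex in 973 genes and from the endodermis in 5118. The meristematic cortex differed from the endodermis in 4849. Calls against the mean of both other populations can therefore reflect the endodermis alone. Solyc04g081700.3.1 fell by 6.59 on the log2 scale (SE 0.78) and Solyc09g064750.2.1 fell by 6.47 (SE 0.84), with Benjamini-Hochberg adjusted p of 2.25e-07 and 1.17e-06 in edgeR's quasi-likelihood test. Solyc01g110890.1.1 averaged 5.6 ± 5.56 CPM (SD, n = 6) against at most 0.092 CPM in the other marked populations, with 6.49 CPM in 35S. Solyc09g097890.2.1 averaged 18.1 ± 15.8 CPM (SD, n = 6), with 17.8 CPM in 35S. In the field meristematic cortex, Solyc01g066457.1.1 averaged 13.9 ± 8.11 CPM (SD, n = 5) against at most 0.809 CPM, and Solyc03g097610.3.1 averaged 16.4 ± 17.7 CPM (SD, n = 5) against at most 1.73 CPM. Solyc06g054320.1.1 and Solyc04g051427.1.1 had no meristematic cortex count (up to 0.0921 CPM possible). That population had 941 genes higher and 1149 lower (45% higher, 32.1% in DESeq2, and 1192 higher and 1151 lower without field endodermis library 1), and 307 higher and 654 lower when joined. The meristematic zone count when joined was 656 higher and 1085 lower, and 83 genes were called there with the abundant gene share as a covariate.

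Whether an enrichment itself differed between field roots and plate root tips was tested as an interaction over 20887 genes; growth condition, age and root part differ together in this comparison. In simulated counts for the endodermis, 63.8% of unchanged genes with an empty group had p under 0.05, and such a group was present for 20.9% of higher calls for the endodermis, 22.6% for the meristematic zone and 19.4% for the meristematic cortex. For the endodermis 693 enrichments were higher in the field and 1315 lower, and 1359 and 1495 without plate endodermis library L. The total of 2008 was 157 with the abundant gene share as a covariate and 777 against 35S. Solyc06g048860.2.1 averaged 35.2 ± 26.6 CPM in field endodermis (SD, n = 5) and Solyc06g005050.3.1 averaged 16.3 ± 12.1 CPM (SD, n = 5), and neither had a count in plate endodermis. Solyc03g111400.1.1 and Solyc05g008480.3.1 had no count in field endodermis and averaged 8.72 and 35.9 CPM in plate endodermis. For the meristematic zone 328 enrichments were higher in the field and 127 lower, a balance that single libraries moved: it was 319 and 329 without plate endodermis library L, and 217 and 182 without field endodermis library 6. Without plate meristematic cortex libraries K, S and T the lower count was 208, 241 and 201. Solyc05g051220.3.1 fell by 3.39 on the log2 scale (SE 0.54) and Solyc02g091270.3.1 fell by 3.47 (SE 0.70), with Benjamini-Hochberg adjusted p of 0.000758 and 0.00861 in edgeR's quasi-likelihood test, and both reached their highest means in field endodermis (9904 and 6314 CPM). Solyc02g083480.3.1 averaged 43.7 ± 24.7 CPM (SD, n = 6) and Solyc02g081890.3.1 averaged 8.78 ± 7.2 CPM (SD, n = 6) in field meristematic zone, against 0.0139 and 0 CPM in plate meristematic zone and 10.6 and 13.3 CPM in plate meristematic cortex. For Solyc02g081890.3.1, 3 of the 6 field meristematic zone libraries were above the mean of the other populations, 6.66 CPM. For the meristematic cortex 966 were higher and 1270 lower, and 1413 were called against 35S. Solyc04g076190.1.1 averaged 92.2 ± 76.1 CPM (SD, n = 5) and Solyc12g010680.2.1 averaged 12.6 ± 9.21 CPM (SD, n = 5) in the field and had no count in the plate libraries of that population. For Solyc12g010680.2.1, 4 of the 5 field libraries were above the mean of the other populations, 6.81 CPM. Solyc03g044625.1.1 and Solyc06g043260.2.1 averaged 0.0516 and 0.0258 CPM in field and 7.35 and 10.3 CPM in plate meristematic cortex. DESeq2-style size factors moved the share of higher calls from 34.5% to 48.7% for the endodermis and from 43.2% to 31.3% for the meristematic cortex, and in DESeq2 the shares were 52.8% and 33.1%. DESeq2 called 1308 for the meristematic zone. The meristematic zone count of 455 was 86 with the abundant gene share as a covariate and 30 against 35S. It was 231, 206, 117 and 180 without plate meristematic zone libraries H, L, O and R, and 291, 271, 277 and 289 without field meristematic zone libraries 1, 2, 4 and 6. In the same order of libraries, higher calls were 159, 132, 69 and 120 and then 218, 205, 201 and 217, and lower calls 72, 74, 48 and 60 and then 73, 66, 76 and 72. Without field meristematic zone library 3 lower calls were 75.

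Called genes of the same population in field and plate libraries overlapped more than independent lists would for the endodermis and the meristematic zone, and no more than that for the meristematic cortex, where genes called in opposite directions exceeded that number. Of the genes higher in the endodermis against the other 2 populations, 727 were shared, where independent lists would share 276, and 226 lower genes were shared, 2.16 times the number for independent lists. For the meristematic zone 171 higher and 405 lower genes were shared, against 69.7 and 45. For the meristematic cortex 29 higher and 14 lower genes were shared against 30.5 and 17.9, while 123 genes higher on plates were lower in the field, where independent lists would give 31.1, and 23 lower on plates were higher in the field, against 17.5. Such opposite calls numbered 115 and 23 for the endodermis, against 221 and 131, and 1 and 23 for the meristematic zone, against 42.9 and 73.3. Log2 fold changes correlated at r = 0.2 for the endodermis, 0.33 for the meristematic zone and -0.0683 for the meristematic cortex across genes, which are not independent replicates. These overlaps use separate libraries for each list and were chosen after the data were seen. The share of counts in the 10 most abundant genes of each table fell from endodermis to meristematic cortex to meristematic zone in both experiments. It was 53.4%, 42.7% and 13% on plates and 42.5%, 11.6% and 2.94% in the field. The overlaps for the endodermis and the meristematic zone therefore cannot be told apart from that share. The meristematic cortex share lay nearer that of the endodermis on plates and nearer that of the meristematic zone in the field. Its opposite calls therefore cannot be told apart from that share either.

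In potted plants, lateral roots of the meristematic cortex line were compared with those of the cortex line. Solyc01g087410.3.1 averaged 885 ± 663 CPM in the meristematic cortex (SD, n = 3) against 75.2 CPM in the cortex (log2 fold change 3.56, SE 0.62, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00142). Solyc01g100690.3.1 averaged 54.8 ± 69.1 CPM (SD, n = 3) and had no cortex count. Solyc03g120570.3.1 (63.9 CPM in the cortex) and Solyc07g063690.1.1 (54.5 CPM) had no meristematic cortex count (up to 0.387 CPM possible). In all 6 genes were higher and 78 lower of 20586, and 10 and 114 without adventitious cortex library X. Without meristematic cortex libraries E and L 3 and 17 were higher. DESeq2 called 172, with 24.4% higher against 7.14%. The 10 most abundant genes of the pot table held 12.7% ± 6.99 of lateral meristematic cortex counts (SD, n = 3) and 6.3% ± 0.823 of lateral cortex counts (SD, n = 3). That share was not run as a covariate here. Simulated counts of this design recovered 0% of 4-fold and 39% of 16-fold changes, and 41.9% of unchanged genes with an empty group had p under 0.05. The series' design text states that 4 pot samples remained after the submitters' filters, fewer than analysed here.

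Adventitious roots, which arise from the hypocotyl, were compared with lateral roots within the cortex line. Solyc08g061250.3.1 averaged 18950 ± 12140 CPM in adventitious roots (SD, n = 4) against 618 CPM in lateral roots, and Solyc04g005290.3.1 averaged 1652 ± 994 CPM (SD, n = 4) against 55.9 CPM. Their log2 fold changes were 4.94 (SE 0.67) and 4.89 (SE 0.55), with Benjamini-Hochberg adjusted p of 0.00904 and 7.28e-07 in edgeR's quasi-likelihood test. Solyc01g073755.1.1, at 104 CPM in lateral roots, had no adventitious count (up to 0.133 CPM possible), and Solyc02g083730.3.1 averaged 0.0211 ± 0.0421 CPM (SD, n = 4) against 19.8 CPM. In all 16 genes were higher and 17 lower, and 71 were called without adventitious library X (18 higher and 53 lower). Without lateral cortex libraries O, X and Z these were 10 and 12, 9 and 14, and 12 and 11. More were higher than lower without adventitious library Z (20 and 16) and without meristematic cortex libraries AA (18 and 15), E (16 and 15) and L (17 and 15), and 19 each way were called without adventitious library O. DESeq2 called 582, with 27% higher against 48.5%. The 10 most abundant genes of the pot table held 14.1% ± 5.21 of adventitious cortex counts (SD, n = 4) and 6.3% ± 0.823 of lateral cortex counts (SD, n = 3). That share was not run as a covariate in pots, so these calls cannot be told apart from it.

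In rice, the RSS1 line differed from the other marked populations in 4140 genes higher and 3800 lower of 20353, while endodermis, vasculature and meristematic cortex were called different from one another in at most 5 genes. Os02t0722300 averaged 18.3 ± 3.51 CPM in RSS1 (SD, n = 3) against at most 1.43 CPM in the other marked populations, with 21.7 CPM in 35S, and Os01t0937050 averaged 8.14 ± 4.68 CPM (SD, n = 3) with no count in the others. Os03t0147550 and Os06t0514800 had no RSS1 count (up to 0.0598 CPM possible) and averaged 14.8 and 6.53 CPM in the others. Pair by pair, endodermis and meristematic cortex differed in 1 gene, endodermis and vasculature in 4, and vasculature and meristematic cortex in 5, and each differed from RSS1 in 6634 to 7313. With the others joined, 3886 genes were higher and 3936 lower in RSS1, and 5096 were called against 35S. The 10 most abundant genes held 19% of RSS1 counts, against 80.6% to 82.9% in the other marked populations. That share was not run as a covariate in rice, so these calls cannot be told apart from it.

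Rice endodermis libraries were set apart by Os02t0532300, at 440 ± 32.2 CPM (SD, n = 3) against at most 16.3 CPM elsewhere (log2 fold change 5.47, SE 0.15, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.99e-17). Os02t0649900 averaged 12.2 ± 2.66 CPM there (SD, n = 3) and 9.09 ± 4.51 CPM in the meristematic cortex (SD, n = 4), where it was also called. Os02t0756800 had no endodermis count (up to 0.446 CPM possible), and Os03t0328000 fell by 3.78 on the log2 scale (SE 1.06), to 35.3 ± 29.6 CPM (SD, n = 3). The compared populations ranged from 36.8 CPM to 2445 CPM (vasculature), and against 35S its log2 fold change was 0.94. Vasculature libraries held more Os07t0162450 (16.3 ± 9.84 CPM, SD, n = 3) and Os08t0109250 (6.83 ± 6 CPM, SD, n = 3), and no count of Os08t0185300 or Os03t0840200 (up to 0.673 CPM possible). In the meristematic cortex Os08t0205125 averaged 5.91 ± 3.08 CPM (SD, n = 4), with library 2B, at 1.33 CPM, under the compared mean of 1.36 CPM, while Os09t0516451 fell by 3.12 on the log2 scale (SE 0.74) and Os01t0602400 fell by 2.67 (SE 0.52). Calls were 730 higher and 223 lower in the endodermis, 307 and 162 in the vasculature, and 521 and 146 in the meristematic cortex. Against 35S they were 9802, 9425 and 9981 in all. With the other populations, RSS1 among them, joined into 1 group, edgeR called 1, 1 and 0 genes. The designed contrasts had 4949, 3969 and 4780 genes at an unadjusted p under 0.05 in edgeR, and DESeq2 with a local dispersion trend called 1350, 750 and 923 in them. Of the genes named here for these populations, Os02t0532300 alone passed when joined. Relabelling libraries among the 3 populations, with RSS1 in place, often gave as many designed calls as the given labels (13, 66 and 59 of 100 splits). Without endodermis library 2 the count was 367 (267 higher and 100 lower), and without vasculature library 2 it was 183 (136 higher and 47 lower). Without vasculature library 3 higher calls were 203. Without meristematic cortex library 1B or 2B the count was 429 or 436, with 346 or 355 higher and 83 or 81 lower.

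Accessible chromatin was compared between the 10 tomato populations by peak number and by peak overlap. The 39 libraries held 262110 peaks, from 3109 to 14826 each. Quiescent centre libraries averaged 9148 ± 3929 peaks (SD, n = 4), the highest mean, and meristematic cortex libraries 5216 ± 732 (SD, n = 4), the lowest. Population accounted for a share of 0.154 of the variance of log10 peak number, which did not exceed chance (permutation test, 100000 draws, p = 0.797, and p = 0.946 when labels were permuted only among libraries with the same letter). The letters of the 3 xylem libraries differ between title and description, and the latter were used; with those of the titles the permutation p was 0.932. Peak sets of the same population shared bases with a mean Jaccard index of 0.161 over 57 pairs, against 0.162 over 684 pairs of different populations, and the difference of -0.00136 was within chance (permutation test, one-sided, p = 0.73). The highest Jaccard index within a population was that of the meristematic cortex, 0.209 over 6 pairs against 0.179 with other populations, and the lowest that of the quiescent centre, 0.108 against 0.134. Neither was tested on its own.

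**Figure D3:**
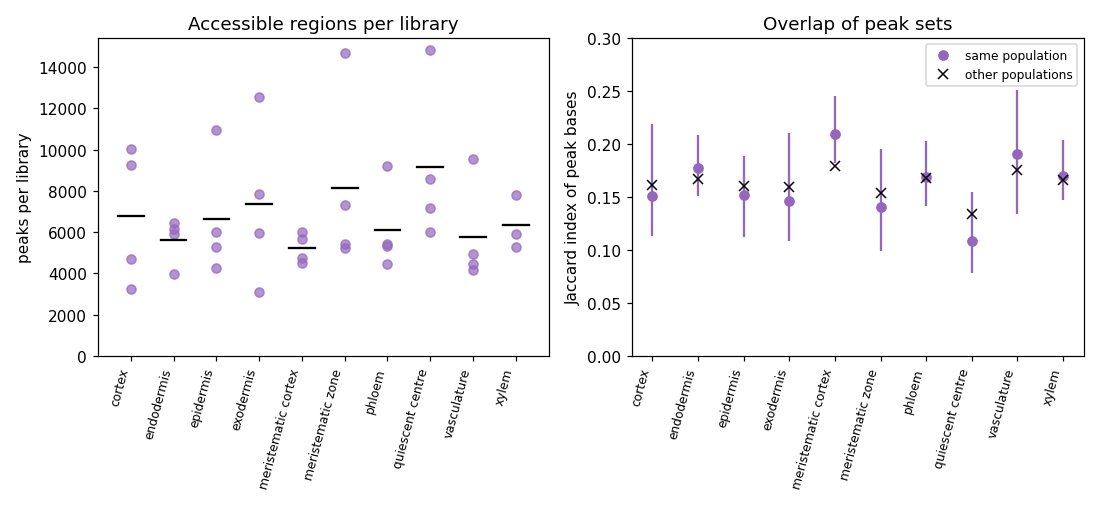
Left, peaks per ATAC library (y axis) by population (x axis), with group means as black bars; right, Jaccard index of peak bases (y axis) for pairs within a population (point, mean; line, lowest to highest) and the mean with other populations (cross). Libraries range from 3109 to 14826 peaks, and the within mean spans 0.108 to 0.209.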

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

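All tests in this part were chosen after the results they bear on were seen, except the field-minus-plate interactions and the comparison of each library with its group, which were set beforehand.

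In single libraries, 15 values stood far from the rest of their group out of 121 groups examined, where chance gives about 1 in 20, or 6.05. The 121 include named genes with 0 CPM in every library of the group, which can give no such value, so 6.05 is too high. For a single value above 0 among zeros the rate of 1 in 20 need not hold. Plate cortex library G held 67383728 counts against 131914 to 8104014 in the others. ACT2 library L had 2.78% of counts in the 10 most abundant genes against 3.14% to 3.21%. Rice meristematic cortex library 2B held 3812098 counts against 4252076 to 4321173. ATAC vasculature library R had 9540 peaks against 4140 to 4941.

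Among named genes, Solyc04g076190.1.1 stood at 119.2 CPM in plate cortex library R (others 8.335 to 28.41). Solyc08g081350.2.1 stood at 63.75 CPM in meristematic cortex library S (0.3035 to 1.748), and Solyc09g072640.3.1 at 74.38 CPM in endodermis library G (0.4611 to 4.028). Solyc12g011130.2.1 and Solyc03g121360.1.1 were both at 1.122 CPM in xylem library I (0 to 0.2781). Solyc04g047727.1.1 reached 110.1 CPM in quiescent centre library P (0.5108 to 41.43). In the field, Solyc09g097890.2.1 stood at 49.54 CPM in meristematic zone library 5 (7.054 to 16.8) and Solyc06g043260.2.1 at 0.1291 CPM in meristematic cortex library 2 (0 in the others). In adventitious cortex library Z of the pots, Solyc02g083730.3.1 stood at 0.08427 CPM (0 in the others). In rice meristematic cortex, Os08t0205125 was at 1.334 CPM in library 2B (6.875 to 7.752) and Os09t0516451 at 2.448 CPM in library 1B (0 in the others).

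Enrichment differed between field roots and plate root tips in 2008 genes for the endodermis, 455 for the meristematic zone and 2236 for the meristematic cortex, by the interaction itself. Among 40 splits of the libraries, 1, 7 and 1 gave as many (highest other 565, 862 and 1156). By a share under 0.05, without correction for the populations tested, chance was excluded for the endodermis and the meristematic cortex. It was not excluded for the meristematic zone. A share of 1 in 40 is the smallest these splits can give. With endodermis libraries kept in place, 4 of 40 gave as many for the meristematic zone (highest other 755) and 1 of 40 for the meristematic cortex (953).

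Random labels alone gave many calls on the plates as designed, with medians of 499 to 846 genes over other splits. As many genes as under the given labels were called in 1 of 40 splits for the exodermis (2318, highest other 1343), the meristematic cortex (1871, 1671), the endodermis (2577, 1220) and the quiescent centre (2051, 1498). The number was 2 for the epidermis (1354, 2101), cortex (1480, 1554) and vasculature (1582, 1759), 3 for the phloem (1637, 1805) and meristematic zone (1226, 1333), and 8 for the xylem (975, 1256). These splits also scatter the exodermis libraries, which differed from each population except the cortex in 892 to 1782 genes. With the exodermis in place, as many were called in 1 of 40 splits for the endodermis (highest other 1862), meristematic cortex (1420), cortex (1422) and phloem (1466), 2 for the epidermis (1514), vasculature (1663) and quiescent centre (2052), 4 for the meristematic zone (1977) and 15 for the xylem (1680). A share of 1 in 40 is the smallest these splits can give, and no correction was made for the 10 populations tested. Only by that uncorrected share, under 0.05, was chance excluded for the designed count of the exodermis, with 1 kind of split. It was excluded in the same way, by both kinds of split, for the endodermis and the meristematic cortex with all libraries. With the library letter as a block, which the splits ignored, each of these counts fell by more than 1.5 times, as listed below. Differences between letters are therefore not excluded. The 1449 and 1676 endodermis calls without library G or R lay below the highest other with the exodermis in place, and the 953 meristematic cortex calls without library S below both highest others. Those without library K, 1343 higher and 114 lower, lay below the highest other of 1671. For the other populations at least 1 kind of split did not exclude chance. A candidate explanation is compared groups with no count: of simulated unchanged genes with an empty group in the contrast, 26% had p under 0.05, and 33.7% to 71.4% of higher calls had one. Differences between libraries that the groups do not name stay open, and no biological explanation was tested.

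With the other populations joined, as many genes were called in 1 of 25 splits for the epidermis (315, highest other 292), exodermis (448, 292) and endodermis (309, 292). The number was 1 of 29 for the phloem (470, 271), 1 of 44 for the quiescent centre (291, 237) and 2 of 44 for the vasculature (190, 237). For groups of 4 libraries 1 of 25 is the smallest share possible, and another draw called more genes than the vasculature. These shares lie under 0.05 without correction for the 10 populations tested, and only by that measure excluded chance. It was not excluded for the meristematic zone (3 of 25; 108, 292), cortex (11 of 29; 37, 271), meristematic cortex (9 of 29; 52, 271) or xylem (12 of 29; 23, 271). Draws were made in 2 rounds, the second because 20 splits cannot give a share under 0.05, and all were counted.

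Chance was excluded for the exodermis against the endodermis (1 of 35; 1342, highest other 47), and in the field for the endodermis (1 of 100; 5601, 2017), meristematic zone (1; 2590, 1504) and meristematic cortex (4; 2090, 2498). These shares too lie under 0.05 without correction, and another split called more genes than the field meristematic cortex. With endodermis libraries kept in place, 1 of 100 splits gave as many for the field meristematic zone (highest other 1781) and for the meristematic cortex (2077). The medians over the other splits were 1116 and 1000. In rice chance was excluded for RSS1 (1 of 100; 7940, highest other 1322). As many were called for the endodermis in 2 (953, 7942), the vasculature in 3 (469, 842) and the meristematic cortex in 1 (667, 327), but these splits also scatter the RSS1 libraries, which differed from all 3, and say nothing of differences among the 3. With RSS1 in place, 13, 66 and 59 of 100 splits gave as many (highest other 1618, 1630 and 1408), so chance was not excluded for these populations. In pots, adventitious against lateral roots gave 33 calls and 2 of 35 splits as many, the real one and 1 other with more calls, so chance was not excluded. The 10 splits for meristematic cortex against cortex are too few for a share under 0.05 (1 of 10; 84, highest other 1).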

How the results depend on the processing

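The joined populations, the fit without shallow libraries, the abundant gene share as a covariate, the summed libraries, the ATAC letters of the titles and the local DESeq2 trend in rice were chosen after seeing the data; the other alternatives were set beforehand. The gene lists, promoter peaks and peak scores were not run, for want of gene names, gene positions and scores in the columns used. The cause of a change was not tested unless stated. All 17 counts run without libraries under 500000 counts stayed within 1.5 times, as did all 11 plate counts with libraries Ta and Tb summed (quiescent centre 1756, vasculature 1230) and 22 of 23 with DESeq2-style size factors, where the xylem count rose to 1865. Those factors moved the median log2 fold change over all genes from -0.233 to 0.00446 for the field-minus-plate endodermis and from -0.0749 to 0.367 for the xylem. In DESeq2 the share of higher calls on plates ran from 15.6% (meristematic zone) to 82.3% (xylem), against 76.3% and 80.6%, so the balance of higher and lower plate calls depended on the tool.

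DESeq2 called 1308 genes for the field-minus-plate meristematic zone, 970 for plate endodermis, 876 epidermis, 742 meristematic cortex, 1029 vasculature, 2430 exodermis against endodermis, 582 adventitious against lateral, 172 pot meristematic cortex against cortex and 750 rice vasculature. The rice fit used a local dispersion trend, chosen after the counts with both trends were seen, because the parametric trend converged on some computer settings and not on others. Where it converged, all 4 rice counts were lower and that of the vasculature lay within 1.5 times of edgeR's. With no low-count filter there were 2253 in the cortex, 2419 epidermis, 2078 meristematic zone, 1919 xylem, 102 adventitious against lateral and 169 pot meristematic cortex against cortex. With no fold minimum rice gave 2010 (endodermis), 1805 (meristematic cortex) and 1047 (vasculature).

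Against 35S, field meristematic zone gave 13, the field-minus-plate endodermis 777, meristematic cortex 1413 and meristematic zone 30, and rice endodermis 9802, meristematic cortex 9981, vasculature 9425 and RSS1 5096. Reversed there were Solyc01g110890.1.1 (-0.28), Os03t0328000 (0.94), Os02t0722300 (-0.24) and Os03t0147550 (0, with no count in either group). Against 35S and ACT2 there were 493 in the epidermis, 876 exodermis, 146 meristematic zone, 1025 vasculature and 1720 xylem. Of named genes, counted in each contrast, 19 did not keep an adjusted p under 0.05 against 35S and ACT2 and 21 did. These numbers were 10 and 26 against 35S alone, 35 and 33 with the abundant gene share as a covariate, and 33 and 35 when joined. They were 25 and 51 with the letter or number as a block, 9 and 83 in DESeq2, and 7 and 61 without shallow libraries.

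With the abundant gene share as a covariate, 14 of 17 counts fell: field endodermis 182, field meristematic zone 83, field-minus-plate endodermis 157 and meristematic zone 86, cortex 689, endodermis 255, exodermis 275, exodermis against endodermis 33, meristematic cortex 932, meristematic zone 19, phloem 964, quiescent centre 164, vasculature 858 and xylem 80. This share differs between the groups, so the covariate can also remove group differences. Joined, the counts were 961 in field meristematic cortex, 37 cortex, 309 endodermis, 315 epidermis, 448 exodermis, 52 meristematic cortex, 108 meristematic zone, 470 phloem, 291 quiescent centre, 190 vasculature and 23 xylem, and in rice 1 (endodermis), 1 (vasculature) and, in edgeR, 0 (meristematic cortex, where the designed contrast had 4780 at an unadjusted p under 0.05 in edgeR and 923 calls in DESeq2).

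Library letters and numbers did not pair libraries by the preset rule: same-letter plate libraries correlated at a mean of 0.0282 against -0.00179 for others, with 7 of 95 pairs over 0.1 (permutation p = 1e-04, the smallest they can give), and means were 0.0257 in the field, 0.0117 in pots and 0.014 in rice (permutation p = 0.12 each). With the letter or number as a block the counts were 621 in the cortex, 178 endodermis, 512 epidermis, 682 exodermis against endodermis, 870 exodermis, 33 meristematic cortex, 377 meristematic zone, 501 phloem, 204 quiescent centre, 198 vasculature, 46 xylem and 52 adventitious against lateral.

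Leaving out each library of the tested group in turn (of both groups for pairs and for field minus plate) gave 957 to 1432 in the cortex, 1449 to 2587 endodermis, 1077 to 1285 epidermis, 1519 to 2040 exodermis, 451 to 1270 exodermis against endodermis, 953 to 1761 meristematic cortex, 730 to 934 meristematic zone, 1192 to 1745 phloem, 1446 to 2135 quiescent centre, 1080 to 1613 vasculature and 702 to 848 xylem. Field counts were 5629 to 6034 (endodermis), 1832 to 2134 (meristematic cortex) and 2092 to 2311 (meristematic zone), and the field-minus-plate counts 1430 to 2854, 1784 to 2476 and 117 to 388 in that order. Pot counts were 22 to 71 (adventitious against lateral) and 62 to 88, and rice counts 7325 to 7839 (RSS1), 367 to 908 (endodermis), 429 to 692 (meristematic cortex) and 183 to 418 (vasculature). Leaving out a library of another compared group went beyond some of these ranges, as in the cortex (1781 without endodermis library G), the xylem (1389 without endodermis library N) and the field meristematic zone (3011 without endodermis library 5), but moved no total by over 1.5 times. It did so for higher or lower calls alone in the xylem, the field-minus-plate meristematic zone and pot meristematic cortex against cortex. These values, and those of libraries of the tested groups that moved higher or lower calls so far, stand with each result. The ATAC share of variance was 0.0996 to 0.219, and the Jaccard difference -0.00323 to 0.00108, with other signs without cortex library O (0.000243), exodermis library M (0.000591) and quiescent centre libraries K (0.00108), P (8.18e-05) and S (9.86e-05). It was 0.000477 for overlaps of 1 base and 0.000582 for 50% of both peaks, and no setting brought it past chance.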

Other observations

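The gene set below, its tests and the comparison with the unassigned library were chosen after the data were seen.

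On plates, 27 genes were higher in all 10 marked populations than the mean of the constitutive lines. They took 58.2% ± 8.19 of xylem counts (SD, n = 5) and 13.9% ± 1.71 of meristematic zone counts (SD, n = 4), against 3.48% ± 1.49 in 35S (SD, n = 4) and 3.22% ± 0.286 in ACT2 (SD, n = 4). Their median log2 fold change ran from 2.17 in the meristematic zone to 5.15 in the endodermis. In the field, 26 of them were called higher than 35S in the endodermis (median log2 fold change of the 27 genes 7.31), 23 in the meristematic cortex (4.39) and 5 in the meristematic zone (1.41), where 25 had a log2 fold change above 0. The set includes Solyc08g061250.3.1 and Solyc04g005290.3.1, which were higher in adventitious roots. It also includes Solyc02g091270.3.1, named above for the field-minus-plate meristematic zone.

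A hypothesis is that marked lines share RNA in fixed proportions. In the field libraries, which did not choose the genes, the spread of their ratios lay at percentile 68 of 1000 random lists (0.808 against a median of 0.728). A spread at or above the median of the random lists was the outcome set down as going against the hypothesis, and this value met it. The outcome was counted as undecided instead, because few of the genes were called in the field meristematic zone. The low median fold change in the field meristematic zone leaves more room there for RNA that 35S libraries also hold, so this may not bear on the shared part. In field endodermis and meristematic cortex alone, a pair chosen after that percentile was seen, the spread lay at percentile 0.4 (0.379 against 0.853), as the hypothesis needs. On plates it lay at percentile 0 (0.308 against 0.725), but the genes were chosen there. Genes regulated together would give the same, which was not tested, so the hypothesis stays open. Shallow libraries were not the cause, since all 27 stayed without libraries under 500000 counts. For the shared controls, unchanged simulated groups gave 0 genes in all 10 and 1 in 2 or more, and independent lists 1.78e-11. Dividing the populations between the 2 constitutive lines gave 0 and 0, because 0 or 1 members were called in the meristematic zone against 35S or ACT2 alone, against 22 to 27 in the others. Their median log2 fold change there was 2.09 and 2.14, against 2.17 with both lines, so the calls were lost with little change of the fold, and these counts do not show an effect of shared controls.

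The pot library with conflicting labels correlated across genes, which are not independent replicates, at 0.838, 0.773 and 0.784 with lateral cortex libraries O, X and Z and at 0.7, 0.669 and 0.762 with lateral meristematic cortex libraries AA, E and L. It held 74.3 CPM of Solyc03g120570.3.1, which ranged from 48 to 77.2 CPM in lateral cortex and had no count in lateral meristematic cortex. It held 36.6 CPM of Solyc07g063690.1.1 (31.6 to 103 and 0), 136 CPM of Solyc01g087410.3.1 (52.3 to 113 and 154 to 1380) and 8.32 CPM of Solyc01g100690.3.1 (0 and 1.43 to 128).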
